A study of Mus musculus with 8 samples.

How the data were processed

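Liver mRNA was sequenced in 8 samples of C57 mice in 3 groups: CTRL (2 samples), APAP_PBS (3) and APAP_MSC (3). Per the labels' protocols, total RNA was extracted with Trizol, mRNA was taken up on oligo(dT) beads, fragmented, and made into Illumina libraries with a NEBNext Ultra kit. Selection for poly(A) tails keeps mRNA and leaves most other RNA out. The labels state no strand setting, so reads of a gene and of an antisense partner cannot be told apart.

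The authors deposited 1 table of 22183 mouse Ensembl genes with an estimated count and an FPKM value for each sample. Reads were handled with fastp 0.18.0, per the submitters' processing notes. The aligner, the quantifier, the genome build and the annotation are not given in the sources used here. Per the file headers, the deposited count columns hold estimated counts. Over all 22183 genes, those at 0 included, 6.39% to 7.46% of the values per sample are not exactly whole, and these were rounded to whole numbers before any count test. FPKM, a fragment count scaled to gene length and library size, is the second unit the authors deposited; it was used only as an alternative, on the log2(FPKM + 1) scale, which understates changes of low genes. Estimated counts that are not whole mean that some reads were shared out between genes, so values of near-identical copies are uncertain. Symbols came from the GENCODE M21 annotation of GRCm38, which matched 22128 of the 22183 IDs; the build of the authors' own annotation may differ, and Cxcl1 coordinates are those of GRCm38. No column of the table was left unused.

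Totals per sample ranged from 16261200 to 24516500 counts. A level of 3 counts, the limit that a count of 0 allows, is 0.122 to 0.184 CPM at these depths; it covers counting error only. Groups were taken from the sample titles. Genes were filtered with filterByExpr, which left 12722, and normalised with TMM. The fit was edgeR 4.0.16's quasi-likelihood test (R 4.3.3; glmQLFit with robust estimation, glmQLFTest) with 1 coefficient per group over all 8 samples, so that the groups share an estimate of the spread. Genes passed at a Benjamini-Hochberg adjusted p of 0.05, and the standard error of a log2 fold change was its size divided by the root of the F statistic. The comparisons made were APAP_PBS with CTRL, APAP_MSC with APAP_PBS and APAP_MSC with CTRL.

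The 37 gene lists, the tests and the alternatives were fixed before the data were examined. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on voom values at a preset inter-gene correlation of 0.01, and again with an estimated correlation; adjustment was over the lists within a comparison. Fry was run as a further test and was not in the planned design. The lists cover drug metabolism, NRF2, p53 and ER stress targets, hepatocyte zones, lipid, bile acid, glucose and amino acid metabolism, glycolysis, acute phase, coagulation, chemokines, cytokines, interferon, heat shock, cell cycle, cell death, immediate early, matrix, macrophage repair, circadian and mitochondrial genes, and markers of neutrophils, monocytes, Kupffer, T and NK, B and plasma, endothelial, stellate, cholangiocyte, mesenchymal stromal and erythroid cells. Markers measure transcript level in tissue and are not cell counts.

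The rule for named genes was fixed at the same time. For the first 2 comparisons it takes the 10 largest increases and the 10 largest decreases among called genes whose groups do not overlap and whose mean is at least 5 CPM in the higher group, without predicted genes, pseudogenes and IDs without a symbol; for APAP_MSC with CTRL it takes 5 each way. If none passes in a direction it takes the 5 with the smallest p, as values only. Up to 4 members per list with the smallest adjusted p are added, and Cxcl1 is always named. The text names a selection of these, some genes are not reported here, and it names few of the genes of lists with no called member.

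The gene and list tests were also run on simulated data with known answers, drawn from the fit to the real data. Counts were drawn for the genes of each comparison from the samples' means and library sizes, with 200 genes changed by 1.5, 2 or 4-fold. For APAP_PBS with CTRL (12555 genes) the shares recovered were 8.96%, 49.3% and 83.3%, with 4 false among 98 calls. For APAP_MSC with APAP_PBS (12533 genes) they were 26.9%, 58.2% and 95.5%, with 17 false among 137 calls. For APAP_MSC with CTRL (12537 genes) they were 22.4%, 64.2% and 83.3%, with 9 false among 122. Camera found the cholesterol list when it was shifted by 0.5 on the log2 scale, and called 0 of the other 36. These draws took each gene independently, while genes of real libraries vary together. The 0 therefore does not show how often camera at the preset correlation calls unchanged lists in real libraries. When the real APAP libraries were divided in ways other than by treatment, camera called 9 to 18 lists. Each side of these divisions held unequal numbers of APAP_PBS and APAP_MSC libraries. They therefore keep part of any MSC effect and are not data without an effect.

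The alternatives were size factors from DESeq2's median of ratios, library size alone, DESeq2 1.42.0, limma-voom, no filter on low counts, a stricter one (5 CPM in 2 samples), a fit on the 2 groups alone, no robust estimation, the replicate number as a block, a 2-fold minimum, limma on log2(FPKM + 1), an estimated correlation and leaving out each sample in turn. Because 2 comparisons share the APAP_PBS libraries, 60 data sets with an unchanged MSC group were simulated, with genes drawn independently. The 6 APAP libraries were also divided in all 10 ways into 3 and 3. Target sites of miR-186-5p were counted as matches to its 7-base seed in annotated 3' UTRs of the GENCODE M21 transcripts.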

Results

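Gene expression was measured by mRNA sequencing in livers of C57 mice, a common inbred laboratory strain. The labels form 3 groups. CTRL (n = 2) is labelled as control. The treatment text of its samples is the same as for the other groups and describes APAP with or without MSCs. CTRL is thus read as liver without APAP from its label alone. APAP_PBS (n = 3) received APAP, by its usual reading acetaminophen, at 400 mg/kg into the abdominal cavity together with PBS, a salt solution. APAP_MSC (n = 3) received the same dose of APAP and, after 4 hours, MSCs, by their usual reading mesenchymal stromal cells, through the tail vein. Livers were taken at 24 hours. Acetaminophen is a painkiller that at high dose injures the hepatocytes around the central veins of the liver, where cytochrome P450 enzymes turn it into a reactive product. The estimated counts per library summed to between 16261200 and 24516500, and 12722 genes were tested. Expression levels below are TMM-normalised CPM (counts scaled to the normalised library size) as mean ± SD, and fold changes are on the log2 scale. Nothing in the labels says that the samples of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical. Within each group every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom between 13.7 and 71.6, so none was counted as a repeat of another. The first principal component over all 8 libraries held 44.0% of the variance. APAP_MSC replicate 2 lay at -18.7 on it, on the side of CTRL (-44.8 and -68.2), and the other APAP libraries between 16.4 and 37.9. This library correlated at 0.960 and 0.965 with the CTRL libraries, which correlated at 0.957 with each other, and at 0.970 and 0.969 with the other APAP_MSC libraries.

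The first comparison, APAP_PBS with CTRL, asks what APAP given with PBS changed in the liver. The labels do not say whether CTRL received PBS, so effects of APAP and of the injection itself cannot be told apart. Acute phase proteins, which the liver secretes in inflammation, rose: 23 of 26 measured members were higher and 0 were lower. Saa2, a serum amyloid A protein, rose from 8.49 ± 0.425 CPM (SD, n = 2) to 2082 ± 179 CPM (SD, n = 3), a log2 fold change of 7.93 ± 0.22 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 5.9e-09). Enzymes of fatty acid synthesis fell, with 15 of 16 lower, and so did enzymes of cholesterol synthesis, with 17 of 21 lower and 1 higher. Acly, which makes cytosolic acetyl-CoA, fell from 1546 ± 406 to 207 ± 9.83 CPM (log2 fold change -2.90 ± 0.17, edgeR adjusted p = 7.0e-06).

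In all, 546 genes were higher and 760 lower in APAP_PBS than in CTRL (edgeR, adjusted p under 0.05), and 264 and 220 of these changed by at least 2-fold. This split depended on the scaling. With library size as the only scaling the median of all genes moved by 0.24 and the counts were 1620 higher and 371 lower (81.4% higher, against 41.8% with TMM), and with the deposited FPKM values it moved by 0.21 and they were 1154 and 325. The log2 fold changes given here are relative to the TMM scaling.

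Among the acute phase genes, Saa1 (6.45 ± 0.22), Orm2, an orosomucoid (4.23 ± 0.24), Lcn2, an iron-binding lipocalin (5.78 ± 0.44), and Apcs, serum amyloid P (2.19 ± 0.17) rose on the log2 scale. The metallothioneins Mt2 and Mt1, which bind zinc and copper, rose by 8.56 ± 0.77 and 6.84 ± 0.69. Saa1 with Saa2, Mt1 with Mt2 and Orm1 with Orm2 are close copies, so reads could have been split between them and the value of each alone is uncertain. Adjusted over the list alone, 25 of the 26 acute phase genes were higher. The list median was 1.76 (camera adjusted p = 4.7e-31 at the preset correlation; adjusted p = 0.0594 with an estimated correlation).

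In fatty acid synthesis, Fasn, the fatty acid synthase, fell by 3.73 ± 0.39 on the log2 scale, from 2111 ± 857 to 159 ± 41.6 CPM. The fold changes were -4.26 ± 0.66 for Elovl6, -4.16 ± 0.56 for Thrsp, -3.74 ± 0.73 for Scd1, which desaturates fatty acids, -3.64 ± 0.42 for Me1, -2.18 ± 0.15 for Gpam, -2.17 ± 0.26 for Elovl5 and -2.07 ± 0.22 for Acacb. All 16 were lower when adjusted over the list alone. The median was -2.32 (camera adjusted p = 3.1e-20; adjusted p = 0.204 with an estimated correlation). For cholesterol synthesis the median was -0.94 (camera adjusted p = 1.4e-16; adjusted p = 0.0594 with an estimated correlation), with 18 lower and 1 higher adjusted over the list alone. Fdps fell by 1.36 ± 0.13, Pmvk by 1.23 ± 0.12 and Dhcr7, the last enzyme of the pathway in many tissues, by 1.02 ± 0.10 on the log2 scale. Pklr, the liver pyruvate kinase, fell by 2.84 ± 0.27.

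Camera called 8 lists of hepatocyte metabolism lower at the preset correlation and 0 of them with an estimated one. Of 21 conjugation enzymes, which attach polar groups to drugs, 10 were lower and 0 higher (16 and 1 adjusted over the list alone), with Gstt1 at -1.05 ± 0.12. Of 14 markers of pericentral hepatocytes, 6 were lower and 0 higher (10 and 0 adjusted over the list alone), with the ammonium transporter Rhbg at -2.30 ± 0.36 and Gulo, the last enzyme of vitamin C synthesis, at -1.08 ± 0.19. Among 21 cytochrome P450 and related genes, 6 were lower and 3 higher: Cyp3a11 fell by 1.31 ± 0.15 and Cyp2f2 by 1.17 ± 0.16, while Cyp3a13 rose by 1.63 ± 0.16. Bile acid genes had 7 lower and 1 higher of 20, with the transporter Slc10a1 at -1.33 ± 0.18 and Cyp7b1 at -1.90 ± 0.30. Fatty acid oxidation genes had 6 lower and 0 higher of 21, with Ehhadh at -1.47 ± 0.14 and Fabp1, the liver fatty acid binding protein, at -2.02 ± 0.20. Urea cycle and amino acid genes had 5 lower and 1 higher of 19: Ass1 (-0.79 ± 0.14) and Prodh (-1.02 ± 0.11) fell and Glud1 (0.70 ± 0.12) rose. Glucose and glycogen genes had 5 lower and 1 higher of 15, with Gys2, the liver glycogen synthase, at -1.05 ± 0.16 and Pygl, the liver glycogen phosphorylase, at -1.63 ± 0.27. The 13 mitochondrially encoded genes had 0 members called and a median of -0.39. Adjusted over the list alone, 12 genes of the P450 list were lower and 4 higher, with 10 and 1 for bile acids, 6 and 0 for fatty acid oxidation, 8 and 1 for the urea cycle, 6 and 2 for glucose and 5 and 0 for mitochondrial genes.

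For these 8 lists camera gave adjusted p = 1.3e-07 for conjugation, 5.9e-08 for pericentral markers, 0.0411 for the P450 list, 1.1e-04 for bile acids, 0.00157 for fatty acid oxidation, 0.00507 for the urea cycle, 0.00579 for glucose and 4.1e-04 for mitochondrial genes. With an estimated correlation the adjusted p was 0.402, 0.409, 0.447, 0.402, 0.416, 0.443, 0.416 and 0.463 in the same order. The call of the P450 list was lost without CTRL replicate 2 (median -0.32, adjusted p = 0.212), without APAP_PBS replicate 1 (-0.32, 0.0841) and with the stricter low-count filter (-0.38, 0.0694), and that of the mitochondrial genes without CTRL replicate 1 (-0.14, 0.150). The fatty acid oxidation median of -0.17 moved to -0.26 without CTRL replicate 1, to -0.11 without CTRL replicate 2 and to 0.06 with library size alone, where the list was still called lower.

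Camera called 11 lists of inflammation and injury higher at the preset correlation and 0 of them with an estimated one, and in each most members were not called over all genes. Cxcl1, a chemokine that attracts neutrophils and the gene that the series title names, rose from 2.76 ± 0.281 to 38.8 ± 4.09 CPM (log2 fold change 3.80 ± 0.21, edgeR adjusted p = 4.6e-06). Among 17 chemokine ligands 3 were higher and 0 lower: Cxcl1, Ccl6 (1.21 ± 0.29) and Ccl7, which was at 0 CPM in both CTRL libraries and at 2.23 ± 1.76 CPM in APAP_PBS. Of 24 inflammatory cytokines and NF-kB targets 5 were higher, including the adhesion molecule Vcam1 (1.28 ± 0.27) and the interleukin-1 receptor Il1r1 (1.70 ± 0.28). Of 17 immediate early genes, which respond to stimuli within minutes, 4 were higher, including Klf6 (2.01 ± 0.35) and Junb (1.27 ± 0.30). Monocyte and macrophage markers had 5 of 15 higher, with the chemokine receptor Ccr2 at 1.91 ± 0.42 and the lysosomal Cd68 at 1.61 ± 0.33. Neutrophil markers had 2 of 10 higher, among them S100a8, which rose from 0.202 ± 0.219 to 2.60 ± 1.47 CPM. Macrophage repair genes had 2 of 12 higher, with Gpnmb at 7.71 ± 3.91 CPM against 0.236 ± 0.0684. The mean of the myeloid markers was highest in APAP_PBS replicate 1, where S100a9 reached 10.2 CPM against 3.44 and 1.40 in the other libraries of the group; this gene, a neutrophil marker, was chosen after its values were seen.

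Cell death genes had 5 of 19 higher, with Bid (0.92 ± 0.15) and Bcl2l1 (0.79 ± 0.12), which promote and restrain apoptosis respectively. Cell cycle genes had 3 of 28 higher and 1 lower: Mcm6, a replication helicase subunit, rose by 1.22 ± 0.20, while Rrm2, a ribonucleotide reductase subunit, fell by 2.25 ± 0.36. Extracellular matrix genes had 3 of 23 higher. Of 24 ER stress genes 2 were higher, including Ppp1r15a (0.99 ± 0.20), and of 15 heat shock proteins only Hspb1 (4.11 ± 0.87) was called over all genes. No member of these lists other than Rrm2 was lower over all genes. Adjusted over the list alone, the members higher and lower were 3 and 0 for chemokines, 9 and 1 for cytokines, 9 and 0 for immediate early genes, 8 and 0 for monocyte, 3 and 0 for neutrophil and 3 and 0 for macrophage repair genes, 11 and 1 for cell death, 13 and 2 for cell cycle, 10 and 0 for matrix, 8 and 0 for ER stress and 0 and 0 for heat shock genes.

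For these 11 lists camera gave adjusted p = 0.0452 for chemokines, 0.00157 for cytokines, 2.4e-04 for immediate early genes, 7.8e-04 for monocyte markers, 0.0145 for neutrophil markers, 0.0123 for macrophage repair, 5.1e-04 for cell death, 4.1e-04 for cell cycle, 0.00162 for extracellular matrix, 0.00400 for ER stress and 0.00507 for heat shock. With an estimated correlation the adjusted p was 0.416, 0.416, 0.416, 0.416, 0.463, 0.416, 0.402, 0.416, 0.478, 0.447 and 0.463 in the same order, so 0 of the 22 lists called at the preset correlation in this comparison were called with the estimated one. The chemokine call was lost without CTRL replicate 2 (median 1.06, adjusted p = 0.117), without APAP_PBS replicate 1 (0.09, 0.0637), without APAP_MSC replicate 2 (0.54, 0.0545), with library size alone (0.75, 0.272), with the stricter low-count filter (0.05, 0.212) and with the replicate block (0.40, 0.0973), and its median of 0.48 moved to 0.88 without CTRL replicate 1 and to 0.74 without APAP_PBS replicate 2. The neutrophil call was lost without CTRL replicate 2 (1.43, 0.200), without APAP_PBS replicate 2 (1.52, 0.0773) and with library size alone (2.29, 0.123), and its median of 2.05 moved to 3.14 without CTRL replicate 1. The cell cycle call was lost with the stricter low-count filter (0.60, 0.265). The median of the immediate early genes moved from 1.17 to 0.77 without APAP_PBS replicate 1, and that of the matrix genes from 0.90 to 0.54 without CTRL replicate 1. Fry, the test outside the planned design, called acute phase (adjusted p = 1.2e-04) and cell death genes (0.0164) higher. It called cholesterol synthesis (4.0e-04), fatty acid synthesis (0.00343), fatty acid oxidation (0.0164), conjugation and bile acid genes (0.0318 each) and pericentral markers (0.0461) lower. Fry also called periportal markers lower (0.0164), which camera did not call.

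The other 15 lists were not called, with camera adjusted p between 0.0644 and 0.846: cholangiocyte, periportal, endothelial, stellate, Kupffer, T and NK, B and plasma, mesenchymal stromal and erythroid markers, NRF2 and p53 targets, interferon-stimulated genes, coagulation and complement, glycolysis and hypoxia, and the circadian clock. For stellate markers the median (-0.05) and the mean (0.07) differed in sign. Over all genes the members higher and lower were 6 and 3 of 22 for NRF2 targets, 2 and 4 of 15 for periportal, 3 and 1 of 14 for stellate, 1 and 0 of 10 for cholangiocyte, 2 and 1 of 12 for mesenchymal stromal and 0 and 1 of 6 for erythroid markers, 4 and 4 of 19 for glycolysis and hypoxia, 3 and 2 of 24 for coagulation and complement, 1 and 3 of 23 for interferon-stimulated genes, 1 and 1 of 17 for p53 targets and 2 and 0 of 16 for the clock, and 0 in the other 4 lists. The counts adjusted over the list alone were 11 and 3, 2 and 7, 3 and 3, 1 and 0, 3 and 1, 0 and 1, 4 and 4, 4 and 9, 1 and 3, 1 and 1 and 2 and 2 in the same order. Among NRF2 targets Gsta1, a glutathione transferase, rose by 4.40 ± 0.54 and Fth1, ferritin heavy chain, by 1.00 ± 0.15, while Me1 fell. Among periportal markers Ctsc rose by 1.22 ± 0.15 while Ass1 and Cyp2f2 fell. The 3 higher stellate markers were the growth factor Hgf (1.09 ± 0.16), Ngfr (1.38 ± 0.24) and Des (1.18 ± 0.29), and the higher cholangiocyte and progenitor marker was Sox9 (1.28 ± 0.25). Alas2, the erythroid enzyme of heme synthesis, was lower at -1.09 ± 0.26, against the direction of its list, whose median was 2.70. In alternative settings NRF2 targets were called higher in 4 of 15, cholangiocyte markers in 3 and endothelial markers in 2. Interferon-stimulated genes were called lower in 1, and B and plasma cell markers in 2 of 10.

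Outside the lists, the largest increases included Prtn3, a myeloid serine protease (6.64 ± 0.975 CPM against 0.130 ± 0.0826), F13a1, a coagulation factor XIII subunit (5.01 ± 3.99 against 0.0947 ± 0.0675), Sorcs2 (6.28 ± 2.39 against 0.153 ± 0.116) and Derl3, an ER protein (6.75 ± 2.19 against 0.296 ± 0.286). The CTRL values of these genes lie near the level of 3 counts, which is 0.132 to 0.182 CPM in the CTRL libraries, so no fold is given. The largest decreases included Rgs16, which dampens G-protein signalling (-4.46 ± 0.93), Chrna4 (-4.07 ± 0.50), Fabp5 (-4.04 ± 0.87), Hcn3 (-4.03 ± 0.57) and Fam198a (-3.19 ± 0.32). Of the 69 named genes, 42 kept the call without any single library; F13a1, Sorcs2, Gpnmb, Rgs16, Elovl6, Fabp5, Scd1, Gulo, Pygl, Ccl6, Ccl7, Vcam1, Klf6, Junb, Ccr2, Cd68, S100a8, Sox9, Gsta1, Glud1, Ngfr, Des, Mcm6, Ppp1r15a, Hspb1, Ass1 and Alas2 lost it in at least 1 case, 26 of them without CTRL replicate 2 and 18 without CTRL replicate 1. Leaving out 1 CTRL or APAP_PBS library left 175 to 340 genes higher and 303 to 477 lower, with the lowest counts without CTRL replicate 2.

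The second comparison, APAP_MSC with APAP_PBS, asks what the MSC injection changed in APAP-treated liver, and the series title names Cxcl1. Cxcl1 (ENSMUSG00000029380; GRCm38, GENCODE M21, chromosome 5, 90891241 to 90893115, plus strand) was lower in APAP_MSC, at 15.9 ± 3.14 CPM (SD, n = 3) against 38.8 ± 4.09 in APAP_PBS (n = 3) and 2.76 ± 0.281 in CTRL (n = 2). Its log2 fold change was -1.28 ± 0.15 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0340), and each APAP_MSC library lay below each APAP_PBS library. Cxcl1 was the only gene called: 0 genes were higher and 1 lower, 842 genes had an unadjusted p under 0.05, DESeq2 called 17 higher and 24 lower, and limma-voom called 0. The direction was kept in every alternative run, with log2 fold changes from -1.45 to -1.17. The call was lost with limma-voom (adjusted p = 0.0555), with a fit on the 2 groups alone (0.0821), without robust estimation (0.0733), with the replicate number as a block (0.115, where 1 other gene was called), with limma on FPKM (0.129) and when any 1 of CTRL replicates 1 and 2, APAP_PBS replicates 1 to 3 and APAP_MSC replicates 1 and 2 was left out (0.0665 to 0.292). In 31 of 60 simulated data sets with an unchanged MSC group at least 1 gene was called, so 1 called gene is a common outcome in that simulation without any change. With no changed gene, an adjusted p under 0.05 should occur in a share of at most about 0.05 of data sets. The edgeR threshold thus did not hold its rate in that simulation, and the adjusted p of 0.0340 may be too low.

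**Figure D1:**
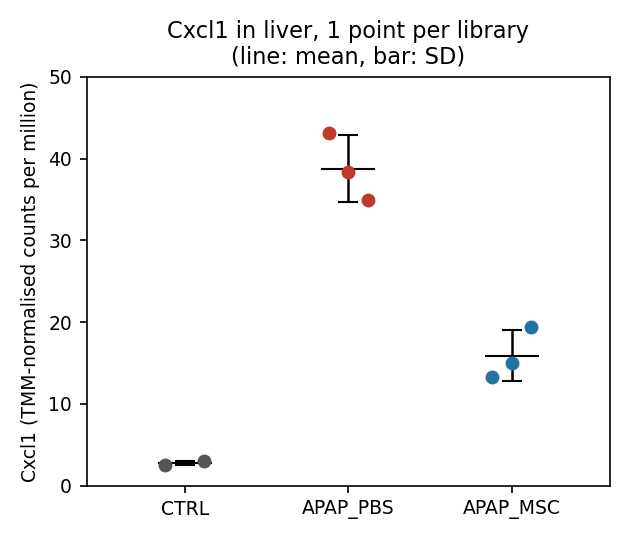
Cxcl1 in each liver library, in TMM-normalised CPM, by group (CTRL n = 2, APAP_PBS n = 3, APAP_MSC n = 3). Each point is 1 library, the line is the group mean and the bar the SD; the APAP_MSC mean of 15.9 lies between the CTRL mean of 2.76 and the APAP_PBS mean of 38.8.

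Cholesterol synthesis genes were higher in APAP_MSC than in APAP_PBS as a group. The median log2 fold change of the 21 members was 0.44, all 21 fold changes lay above 0, 0 members passed over all genes with edgeR and 14 were higher adjusted over the list alone (camera adjusted p = 3.9e-23, and 0.0530 with an estimated correlation). DESeq2 called Nsdhl, Dhcr7, Fdps, Cyp51, Sqle, Fdft1, Lss and Mvd higher over all genes (DESeq2 adjusted p between 7.8e-04 and 0.0286). Fry, a self-contained test of whether the genes of a list move one way on balance, called this list and none of the other 36 (adjusted p = 0.0158); fry was added after the design was fixed. The log2 fold changes were 0.73 ± 0.12 for Nsdhl, 0.62 ± 0.12 for Sqle, the squalene epoxidase, 0.62 ± 0.12 for Lss and 0.54 ± 0.09 for Dhcr7 (edgeR adjusted p between 0.270 and 0.299 over all genes). In the first comparison 20 of the 21 genes had a fold change below 0. Acute phase proteins had a median of 0.18 with 6 of 26 higher adjusted over the list alone and 0 over all genes with edgeR (camera adjusted p = 6.1e-05, and 0.302 with an estimated correlation). DESeq2 called Saa2, Orm1, Orm2 and Saa1 higher over all genes (DESeq2 adjusted p between 1.6e-05 and 0.00600). Saa2 was at 3532 ± 493 CPM against 2082 ± 179 (log2 fold change 0.76 ± 0.13, edgeR adjusted p = 0.270), with Saa1 at 0.63 ± 0.14, Orm1 at 0.64 ± 0.13 and Orm2 at 0.79 ± 0.18. The acute phase median was 0.10 without APAP_PBS replicate 2, 0.29 without APAP_MSC replicate 2 and 0.09 without APAP_MSC replicate 3.

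**Figure D2:**
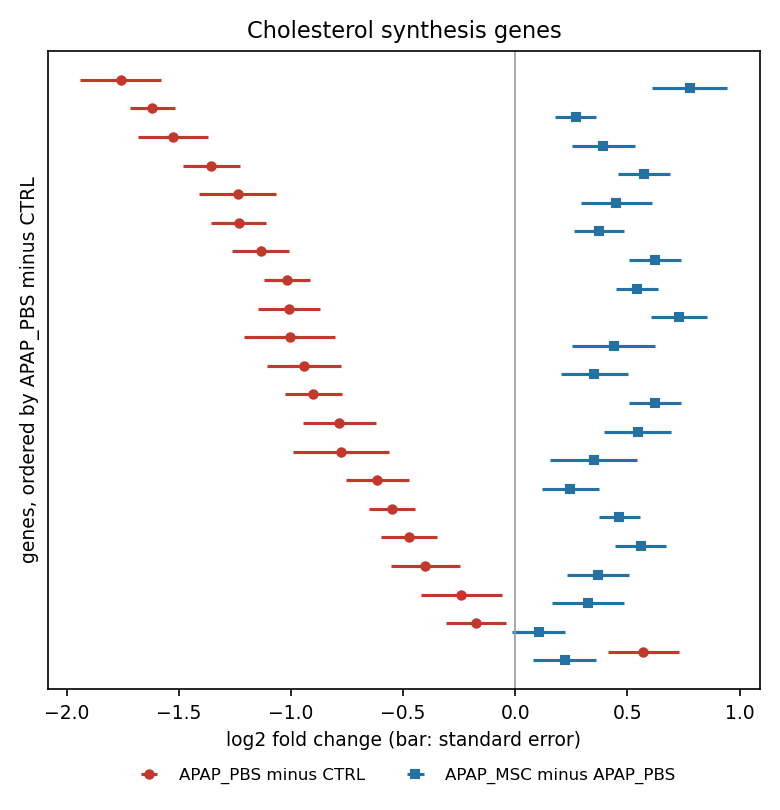
Log2 fold change of each of the 21 cholesterol synthesis genes, 1 row per gene, in APAP_PBS minus CTRL (circles) and APAP_MSC minus APAP_PBS (squares), with bars for the standard error. All 21 squares lie above 0, and 20 of the 21 circles lie below 0.

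Lists of inflammation and injury were lower in APAP_MSC than in APAP_PBS by camera at the preset correlation, though not at an estimated one, with 0 members called over all genes by edgeR. DESeq2 called the members Ccr2, S100a8, Klf6, Sox9, Tagln, Mki67, Btg2 and S100a4 lower over all genes (DESeq2 adjusted p between 0.00297 and 0.0482). For immediate early genes the median was -0.89 (camera adjusted p = 5.8e-12), with Klf6 at -1.19 ± 0.29 and Ccn1 at -1.04 ± 0.27. For cell cycle genes it was -0.51 (1.3e-08), with the proliferation marker Mki67 at -1.89 ± 0.40 and Top2a at -1.84 ± 0.42. Monocyte markers had -0.68 (9.5e-07), with Ccr2 at 1.21 ± 0.0396 CPM against 4.63 ± 2.39 and S100a4 at -2.49 ± 0.62, and neutrophil markers -1.07 (0.00291), with S100a8 at 0.361 ± 0.188 against 2.60 ± 1.47 CPM. The other lists were extracellular matrix (-0.51, 2.5e-06), with Thbs1 at -2.61 ± 0.83 and Tagln at -1.49 ± 0.46, cytokines (-0.33, 4.2e-05), heat shock (-0.33, 4.2e-05), cell death (-0.14, 0.00384) and cholangiocyte markers (-0.70, 5.5e-05), with Sox9 at -1.08 ± 0.21. With an estimated correlation the adjusted p of these 9 lists lay between 0.302 and 0.437. Adjusted over the list alone, 3 immediate early, 3 cell cycle, 3 monocyte, 2 neutrophil and 2 cholangiocyte genes were lower and 0 of the other 4 lists. Without APAP_PBS replicate 1, the library with the most S100a9, the medians were -0.38 for monocyte, -0.24 for matrix, -0.18 for cytokine and -0.46 for neutrophil genes, and the neutrophil call was lost (adjusted p = 0.0524), as it was without APAP_PBS replicate 2 (-0.89, 0.0919) and APAP_MSC replicate 3 (-0.95, 0.120); without APAP_MSC replicate 1 the neutrophil median was -1.80. The cholangiocyte median was -0.40 without APAP_PBS replicate 3.

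Lists of hepatocyte function and Kupffer cell markers were higher by camera at the preset correlation alone, again with 0 members called over all genes. Fatty acid synthesis had a median of 0.51 (camera adjusted p = 1.7e-09), with Fads1 at 0.39 ± 0.12 and Acly at 0.44 ± 0.15. Pericentral markers had 0.44 (1.3e-07), with Rhbg at 0.98 ± 0.34. Fatty acid oxidation had 0.12 (0.00183), the P450 list 0.19 (0.00291), coagulation and complement 0.08 (0.0251) and Kupffer cell markers 0.16 (0.0310). Adjusted over the list alone, 1 pericentral gene was higher and 0 genes of the other 5 lists. With an estimated correlation the adjusted p lay between 0.302 and 0.762, so 0 of the 17 lists called at the preset correlation in this comparison were called with the estimated one. APAP_MSC replicate 2 stood apart: Scd1 was 7667 CPM there against 2169 and 1424 in the other APAP_MSC libraries, Glul, a pericentral glutamine synthetase, 426 against 125 and 79.1, and Hspa1a, a heat shock protein, 2.24 against 40.1 and 78.1; Glul and Hspa1a were chosen after their values were seen. Without that library the medians were 0.22 for fatty acid synthesis, 0.25 for pericentral markers, -0.19 for heat shock and -0.27 for matrix genes, all still called, while the P450 list (0.13, adjusted p = 0.0535), cell death (-0.15, 0.0632), coagulation (0.03, 0.739) and Kupffer markers (0.06, 0.381) were not. The Kupffer call was also lost without APAP_PBS replicate 2, where the median was -0.02, without APAP_MSC replicate 3 (0.09, 0.419) and with the stricter low-count filter (0.14, 0.0542), and the coagulation call without APAP_PBS replicate 1 (0.03, 0.179), without APAP_PBS replicate 2 (0.09, 0.0731) and with the stricter low-count filter (0.07, 0.0636). Further medians that moved were 0.12 for the P450 list and 0.29 for pericentral markers without APAP_PBS replicate 1, 0.33 for Kupffer markers without APAP_PBS replicate 1, 0.31 for Kupffer markers and 0.17 for coagulation without APAP_MSC replicate 1, and -0.51 for heat shock and -0.27 for cell death without APAP_MSC replicate 3.

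**Figure D3:**
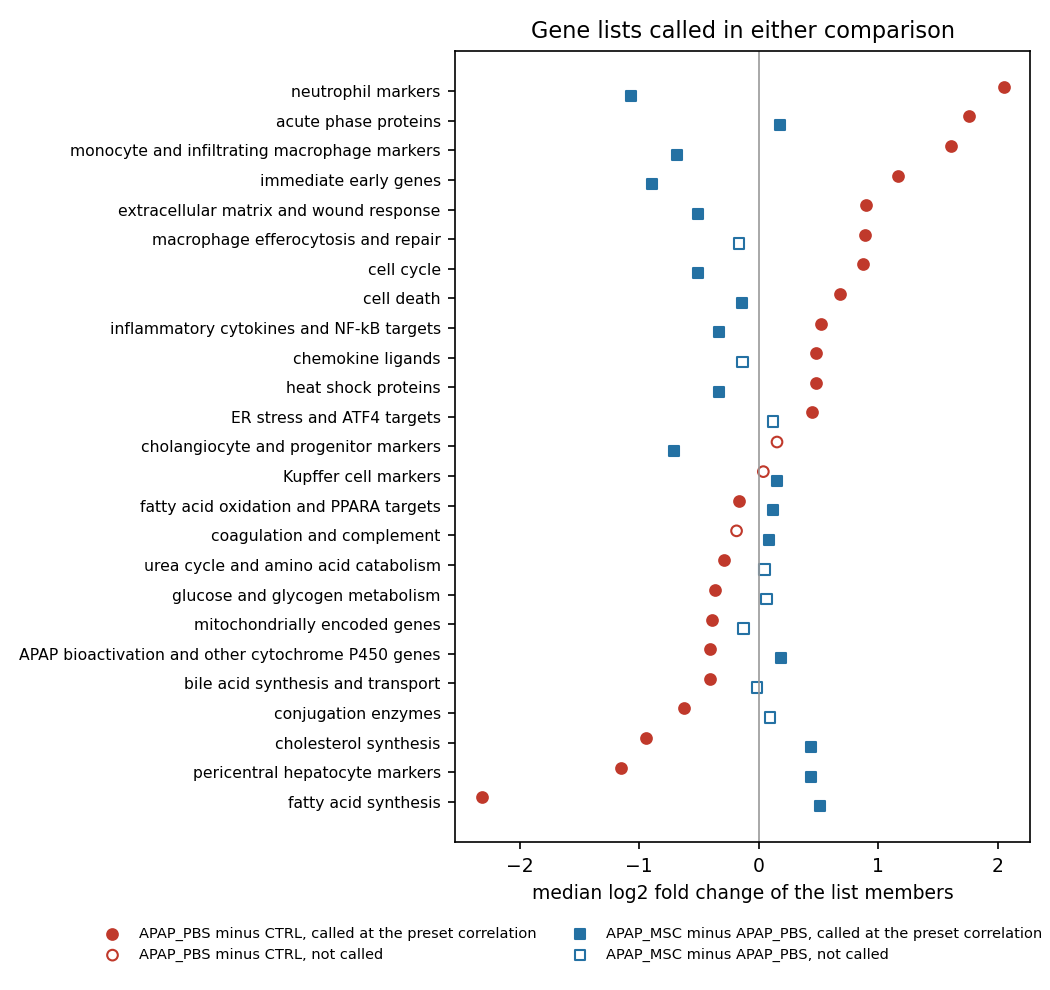
Median log2 fold change of the members of each of the 25 gene lists called at the preset correlation in either comparison, APAP_PBS minus CTRL (circles) and APAP_MSC minus APAP_PBS (squares). Filled symbols mark lists called at the preset correlation of 0.01 and open symbols lists not called; the cholesterol synthesis medians are -0.94 and 0.44.

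The other 20 lists were not called in this comparison (camera adjusted p between 0.0645 and 0.970): p53 targets, endothelial, periportal, stellate, mesenchymal stromal, T and NK, B and plasma and erythroid markers, ER stress, mitochondrial genes, chemokines, NRF2 targets, macrophage repair, glycolysis and hypoxia, the urea cycle, bile acids, conjugation enzymes, glucose, the circadian clock and interferon-stimulated genes. The median, mean and test differed in sign for chemokines (median -0.14, mean 0.11), bile acids, glucose, mesenchymal stromal, stellate, periportal and interferon-stimulated genes. For mesenchymal stromal markers, the list of the injected cell type, the median was -0.01 (camera adjusted p = 0.899). Stellate and mesenchymal stromal markers each had 1 member higher and 3 lower adjusted over the list alone. In alternative settings the chemokine list was called lower in 7 of 15, endothelial markers higher in 6, ER stress genes higher in 5 and NRF2 targets lower in 3. P53 targets and mitochondrial genes were called lower in 2 each, and erythroid markers in 2 of 14. Conjugation, urea cycle, glycolysis and macrophage repair genes were called in 1 each. So were interferon-stimulated genes, lower without APAP_MSC replicate 2 (median -0.24, camera adjusted p = 0.0227). Other members were the stellate genes Hgf (-0.59 ± 0.13) and Ngfr (-0.85 ± 0.20) and the chemokine Ccl7, at 0.479 ± 0.386 CPM against 2.23 ± 1.76.

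The third comparison, APAP_MSC with CTRL, asks what still differed from control liver after APAP and MSCs. Acute phase proteins were higher in 24 of 26 members, with Saa2 at a log2 fold change of 8.70 ± 0.22 (edgeR adjusted p = 3.0e-09), Saa1 at 7.08 ± 0.23, Mt2 at 7.86 ± 0.76, Mt1 at 6.38 ± 0.67 and Lcn2 at 6.29 ± 0.45. Fatty acid synthesis was lower in 11 of 16 members, with Elovl6 at -3.56 ± 0.64, Thrsp at -3.36 ± 0.55, Me1 at -3.07 ± 0.41, Acly at -2.46 ± 0.17 and Gpam at -1.80 ± 0.15. Cholesterol synthesis was lower in 8 of 21 and higher in 1, with Fdps at -0.78 ± 0.13. Cxcl1 was higher, at 2.52 ± 0.21 (edgeR adjusted p = 6.9e-05). ER stress genes were higher in 6 of 24, among them the chaperones Calr (0.74 ± 0.14) and Pdia6 (0.69 ± 0.15). Hcn3 (-3.79 ± 0.56), the acetyltransferase gene Nat8f5 (-3.09 ± 0.32) and Cyp3a11 (-1.35 ± 0.15) were lower, and Gpnmb was at 4.34 ± 2.11 CPM against 0.236 ± 0.0684.

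In this comparison 321 genes were higher and 422 lower (edgeR, adjusted p under 0.05; 133 and 125 by at least 2-fold). With library size as the only scaling the counts were 755 and 236 (76.2% higher, against 43.2%; the median of all genes moved by 0.19), and with FPKM 447 and 207 (68.3% higher; 0.16). Camera called 13 lists: acute phase (adjusted p = 2.2e-39), ER stress (2.4e-05), cell death (0.0176), macrophage repair (0.0176) and endothelial markers (0.0175) higher, and fatty acid synthesis (1.0e-16), conjugation (8.6e-08), cholesterol synthesis (9.0e-07), mitochondrial genes (4.1e-06), bile acids (1.1e-04), pericentral markers (0.00109), glucose (0.00767) and the urea cycle (0.0206) lower. When adjusted over the list alone, 24 acute phase, 7 ER stress, 5 cell death, 2 macrophage repair and 0 endothelial genes were higher, and 14 fatty acid synthesis, 12 conjugation, 11 cholesterol synthesis, 8 mitochondrial, 8 bile acid, 3 pericentral, 7 glucose and 7 urea cycle genes were lower. In the other direction 1 cell death gene was lower, and 2 bile acid, 1 pericentral, 1 glucose, 1 urea cycle and 1 cholesterol synthesis gene were higher. With an estimated correlation the camera adjusted p lay between 0.0516 and 0.756, and 0 were called. Fry called acute phase genes higher (adjusted p = 8.3e-05) and cholesterol synthesis (0.0112), fatty acid synthesis (0.0113), conjugation and bile acid genes (0.0494 each) lower. Fry also called periportal markers lower (0.0210), which camera did not call. The other 24 lists had camera adjusted p between 0.0968 and 0.970, and for the P450 list, stellate markers and the circadian clock the median and mean differed in sign. Among these, B and plasma cell markers (median -0.83) were called lower in 6 of 11 alternative settings, Kupffer markers higher in 3 of 15 and chemokines higher in 2. Another 6 lists were called in 1 setting. Without CTRL replicate 2 the calls of the urea cycle (median -0.18, adjusted p = 0.146), glucose (-0.44, 0.0807), cell death (0.45, 0.0807) and macrophage repair (0.67, 0.0598) were lost, as were those of the urea cycle (-0.15, 0.117) and endothelial markers (0.22, 0.117) without APAP_MSC replicate 3 and of endothelial markers without CTRL replicate 1 (0.14, 0.571) and with the replicate block (0.28, 0.0568). Other medians that moved were pericentral markers at -1.02 without APAP_MSC replicate 2 and -0.44 without APAP_MSC replicate 3, cell death at 0.19 without APAP_MSC replicate 3, mitochondrial genes at -0.22 without CTRL replicate 1 and endothelial markers at 0.53 without CTRL replicate 2. Of 18 named genes 10 kept the call without any single library, and Hcn3, Elovl6, Thrsp, Me1, Calr, Pdia6, Gpnmb and Fdps lost it in at least 1 case. The counts were 657 higher and 733 lower without APAP_MSC replicate 2, 119 and 141 without CTRL replicate 1, and 119 and 154 without CTRL replicate 2.

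Genes called in APAP_PBS against CTRL and called in the opposite direction in APAP_MSC against APAP_PBS were counted last. Cxcl1 was the only such gene, and 0 genes were called in the same direction in both comparisons; independent lists of these sizes would give 0.0429 and 0.0597. DESeq2 gave 29 genes moved back and 5 moved further. Limma-voom, the 2 groups alone, no robust estimation, FPKM and leaving out any 1 library except APAP_MSC replicate 3 gave 0 moved back. Both comparisons use the APAP_PBS libraries with opposite sign, so opposite signs arise with no effect. Over the genes tested, which are not independent replicates, the covariance of the log2 fold changes was -0.158, against -0.0630 to -0.0353 in 60 simulated data sets with an unchanged MSC group, a difference of -0.109 from the simulated mean. The correlation across genes was -0.513 against -0.218 to -0.125, and 81.3% of fold changes of the genes called in APAP_PBS against CTRL had opposite signs against 60% to 65.2%. When the 6 APAP libraries were relabelled in all 20 ways, 2 labellings, the real one included, gave a covariance as low, and the lowest of the others was -0.167. The other labellings are not free of an MSC effect, so they do not give the covariance without it. The 3 APAP_PBS libraries cannot be split so that each part keeps at least 2, so part of the excess may come from shared libraries.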

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

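The covariate of myeloid markers was chosen after the data were seen; the other alternatives were planned. Of 1860 alternative values of single genes 1717 kept direction and side of the threshold, 128 lost and 15 gained a call. Of 1627 list results, judged by camera's direction and adjusted p and not by the median, 1479 kept both, 85 lost and 60 gained a call and 3 reversed. Counted among the gene and list values that kept both are 62 that changed direction where neither value was called. Of 234 values that answer a comparison, most of them counts, 149 were kept, 13 lost a call and 72 moved. A count was taken as kept within 1.5-fold of that of the main fit, and a count of 0 only where it stayed 0. The cause was not tested unless given. APAP_PBS against CTRL (546 higher, 760 lower) gave 1620 and 371 with library size alone, 333 and 460 with a replicate block, 264 and 220 with a 2-fold minimum (a stricter threshold by construction) and 1154 and 325 with FPKM. APAP_MSC against CTRL (321, 422) gave 755 and 236 with library size, 519 and 698 with DESeq2, 124 and 170 with the 2 groups alone (where APAP_PBS against CTRL rose to 765 and 1089), 135 and 186 with the replicate block, 133 and 125 with a 2-fold minimum and 207 lower with FPKM. APAP_MSC against APAP_PBS (0, 1) gave 17 and 24 with DESeq2 and 0 lower with limma-voom, 2 groups, robust estimation off and FPKM. The lists called (22, 17, 13) fell to 0, 0 and 0 with an estimated correlation. Cxcl1 in APAP_MSC against APAP_PBS lost its call at -1.28 with limma-voom, 2 groups and robust off, -1.29 with the replicate block, -1.30 with FPKM and -1.19 with the myeloid covariate. Genes moved back (1) were 29, with 5 moved further, in DESeq2, and 0 with limma-voom, 2 groups, robust off and FPKM.

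Leaving out each library in turn gave 175 to 790 higher and 303 to 920 lower genes in APAP_PBS against CTRL, 119 to 657 and 141 to 733 in APAP_MSC against CTRL, and 0 to 1 higher and 0 to 1 lower in APAP_MSC against APAP_PBS, with 0 to 1 moved back. Cxcl1 stayed between -1.45 and -1.17. List results that reversed in APAP_MSC against APAP_PBS were Kupffer markers without APAP_PBS replicate 2 (median -0.0212, range -0.0212 to 0.33) and, without APAP_MSC replicate 2, coagulation, in the direction of the test only (0.0277, range 0.0277 to 0.17), and interferon genes (-0.24, range -0.24 to 0.11). Shared numbers gave no clear sign of pairing: the deviations of same-numbered APAP libraries correlated at 0.01, -0.01 and -0.06. Those of the CTRL libraries correlated with the same-numbered APAP_MSC libraries at 0.20 and 0.17, and with the same-numbered APAP_PBS libraries at -0.13 and -0.02. Not every sample correlated best with its own number. Depth of 16261200 to 24516500 counts limits low genes: a count of 3 is 0.122 to 0.184 CPM. The planned list tests under DESeq2, limma-voom and robust off were not run, since camera works on voom values that these settings leave as they are.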

Other observations

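The tests on the myeloid covariate, with all or 12 or 13 of its markers, on lists called in opposite directions without APAP_MSC replicate 2, on reordered seed words and AT content, on both explanations of the control libraries, on the covariance under other labellings, and on the cholesterol list over the divisions, with fry and with members adjusted over the list alone, were chosen only after the result was seen.

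The 2 control libraries differed from each other in bile duct genes and in the clock. Dmbt1, a mucin-like gene of ducts and gut, was at 745 CPM in CTRL replicate 1 and 0.0470 in CTRL replicate 2, Krt19, a keratin of bile ducts, at 23.3 and 1.03, and Muc1 at 18.8 and 0.611. The APAP libraries had 108 to 489 CPM of Dmbt1, 6.08 to 24.4 of Krt19 and 4.74 to 20.8 of Muc1. CTRL replicate 2 was thus the lowest of all libraries for these genes. Dbp, a clock output gene, was at 5.84 and 31.4, Arntl, a core clock gene, at 21.8 and 11.6, and Bcl6 at 6.98 and 65.0. The neutrophil-attracting chemokine Cxcl5 was at 13.1 CPM in CTRL replicate 1, 5.42 in APAP_MSC replicate 1 and at most 0.290 in the other libraries. Dbp also varied within APAP_MSC and Bcl6 within both APAP groups: in APAP_MSC replicate 2 they were at 16.2 and 56.7 CPM, against 2.86 and 6.94 in replicate 1 and 5.80 and 8.56 in replicate 3, and in APAP_PBS Bcl6 was at 26.8, 6.21 and 48.8 while Dbp stayed at 3.67, 3.69 and 2.69. These genes were chosen after their values were seen.

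Neither explanation tested for the control difference is decided, because the lists hold the genes in which the difference was first seen and the values restate it. The 16 clock genes differed by a median of 0.92 in absolute log2 difference, against a median of 0.20 for 10000 random lists matched on expression, at percentile 100, which leaves time of day or feeding at collection open. The 10 cholangiocyte markers had a median log2 difference of 2.53 (CTRL replicate 1 minus replicate 2), with Krt19 at 4.46 and Muc1 at 4.89 but Sox9 (0.09), Krt23 (-0.44) and Spp1 (-0.00429) near 0 or below, which leaves more bile duct or gallbladder tissue in 1 library open. The difference does not say which of the 2 libraries was unusual. No other explanation was tested, as the labels put both libraries in 1 group. The counts of changed genes against CTRL rest on these libraries.

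Lower Cxcl1 in APAP_MSC was set against 3 explanations. Shared APAP_PBS libraries: 0 of 60 simulated data sets with an unchanged MSC group gave a log2 fold change as low as -1.28 (simulated range -0.42 to 0.31), the outcome written beforehand as evidence against. The simulation drew Cxcl1 with the spread estimated in the same fit, so it restates the edgeR test and decides nothing more. The simulated data sets called 1982 to 2204 genes in APAP_PBS against CTRL, against 1306 observed, so they may understate the real spread. Fewer neutrophils and monocytes: with the mean of 25 markers as a covariate the fold change was -1.19 (SE 0.23, unadjusted p = 3.7e-04, adjusted p = 1.00) against -1.28 (SE 0.15). With a score from 13 or from the other 12 of the markers, the median of the markers left out moved from -0.65 to 0.21 and from -1.08 to -0.38, so the score moves genes outside it, and Cxcl1 was at -1.08 (SE 0.24) and -1.28 (SE 0.20). The covariate takes a degree of freedom, and the call was lost with a wider error while the fold stayed close to its value. Why the error widened was not tested. The score did not overlap between the 2 groups, at 0.154 to 1.36 in APAP_PBS and -0.419 to 0.0675 in APAP_MSC. The adjusted fold thus rests on extrapolation, and with 1 of the scores the left-out markers still stood at -0.38. Whether fewer such cells account for lower Cxcl1 therefore stays open. miR-186-5p acting through 3' UTR sites: genes with a 7-base site differed in median log2 fold change from genes of matched length and expression without one by -0.0320 (2604 genes, permutation p = 1e-04, the smallest these permutations can give), but matching on AT content left -0.00320 (p = 0.212) and 26 of the 42 orders of the same 7 bases, the seed included, gave a difference as low. The shift is thus not specific to the site, so it neither argues for nor against the miRNA acting on Cxcl1, whose 3' UTR of 592 bases has 1 site, and an effect of the MSCs stays open as a hypothesis.

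Of the 10 divisions of the 6 APAP libraries into 3 and 3, 1, the real one, called as many genes (1, highest other 0), and 2 called as many lists (17, highest other 18). With 10 divisions the share cannot fall under 0.05, and the other divisions keep part of any MSC effect. Fry called the cholesterol list in the real division alone (adjusted p = 0.0158, against at least 0.591 in the others), with 14 against 0 members adjusted over the list alone.

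The lists that moved back towards control were set against 2 explanations. APAP_MSC replicate 2 alone: of the 13 lists called in opposite directions in the first 2 comparisons, 11 kept call and direction without it. The test set before counted all 17 lists called in APAP_MSC against APAP_PBS, 4 of which had not moved back by that measure, and 13 of them kept both, the outcome written beforehand as evidence against. That criterion cannot decide, because camera at the preset correlation called 9 to 18 lists in the other divisions of the APAP libraries. Those divisions held unequal numbers of the 2 groups on each side and so keep part of any MSC effect. They do not show how many lists are called without an effect, so what a kept call says is not known. Without the library the median fell from 0.51 to 0.22 for fatty acid synthesis and from -0.51 to -0.27 for matrix genes, and stayed at 0.42 against 0.44 for cholesterol synthesis and -0.80 against -0.89 for immediate early genes. How much of the pattern rests on that library stays open. Shared APAP_PBS libraries: the covariance of -0.158 lay below all 60 simulated values (-0.0630 to -0.0353), the outcome written beforehand as evidence against. That criterion cannot decide either, because the simulation drew genes independently while real libraries vary together. At most 1 list was called in a simulated data set, against 9 to 18 in the other divisions of the real libraries. Of 20 labellings of the APAP libraries 2, the real one included, gave a covariance as low. The other labellings are not free of an MSC effect. The shared libraries and an effect of the MSCs therefore cannot be told apart here.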
